A study of Rattus norvegicus with 12 samples.

How the data were processed

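Liver RNA of 12 male Sprague-Dawley rats was measured on 12 Affymetrix Rat Genome 230 2.0 arrays, 1 liver per array and no pooling, per the labels' protocols. The 4 groups were control, myclobutanil, propiconazole and triadimefon, with 3 rats each, so the limma p-values measure the spread between animals. The deposited values are a log-like score per probe set. The authors' probe-level summary, normalization, software and log base are not given in the sources used here. Deposited array medians lay between 0.0182 and 0.157, the lowest value was -1.0 and the highest 4.83, and the spike-ins bioB, bioC, bioD and cre rose in order with means of 0.482, 1.10, 2.31 and 3.24 in the median array. The scale is therefore log-like, but its base and centring stay unknown. The plan assumed log2 values; since this could not be settled, the values were used without conversion and no fold change is given. No 2 arrays held identical values.

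Array medians had a range of 0.138, above the median within-group SD of 0.0736, so the arrays were quantile normalized, by a rule set for tables that are not yet normalized. Of 31099 probe sets, 57 control probe sets were left out. The 30% of the remaining 31042 with the lowest mean over all arrays (9313) were left out as dim, which left 21729. The platform annotation, which can be old, gave 1 gene for 20826 probe sets, several for 436 and none for 9780. Symbols were updated through the Entrez ID with a RefSeq table of the GRCr8 assembly for 20758 probe sets, and 68 kept the annotation's symbol. No coordinates are given, as no build belongs to the values. The tested probe sets with 1 gene (16078) covered 11842 genes, each represented by the probe set with the highest mean.

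Each probe set was fitted with limma (version 3.58.1, R 4.3.3) on the 4 group means of all 12 arrays, with 8 residual degrees of freedom and moderated variances with an intensity trend. Benjamini-Hochberg adjustment was over the 21729 probe sets of each of 6 comparisons, and an adjusted p under 0.05 was called. Tests were run in both directions. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15 with pandas 2.3.3. The number of arrays sets the precision. Simulated data held 200 changed probe sets, with the 30 cell cycle genes also shifted by 0.3. Among the 200, the test for myclobutanil against control recovered 49.25% of shifts of 0.3, 89.55% of 0.6 and 100% of 1. Of 184 calls in all, cell cycle genes included, 10 were false. With no change it made 0 calls by limma, with 4.989% of unadjusted p under 0.05. These rates hold for the simulated noise. The real count ran from 30 to 924 with 1 array left out.

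Gene lists were tested with camera of limma (preset correlation 0.01, Benjamini-Hochberg over 26 lists per comparison), which compares a list with the other genes, again with the correlation estimated for each list, and with fry, which tests whether a list moves one way without comparing it with other genes. The lists were CAR and PXR targets, AhR targets, NRF2 targets, fatty acid oxidation with PPAR-alpha targets, cholesterol synthesis, fatty acid synthesis, bile acids, male-biased genes, steroid, retinoid and thyroid hormone metabolism, ER stress, cell cycle, p53, acute phase, glucose, circadian clock, and immediate early with heat shock genes. Marker lists covered hepatocytes, Kupffer cells and macrophages, stellate cells, cholangiocytes, endothelium, leukocytes, blood and pancreas. They held 560 entries, of which 457 were tested, with 440 different genes, 17 of them in more than 1 list, and 6 to 32 tested members per list. The lists were written from general knowledge and not from these samples, and the marker lists describe bulk liver and call no cell type.

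The groups, tests, gene lists, alternatives and the rule for naming genes were set before the data were examined, and so were the tests on other splits of the arrays. For each compound against control the rule names the 10 largest rises and falls among called genes whose groups do not overlap, up to 4 called members of each list or up to 2 with the smallest p where none was called, and fixed genes. Between compounds it names the 5 largest differences each way, the fixed genes and members of called lists. The fixed genes are Cyp3a23-3a1, Cyp1a1, Cyp1a2, Cyp4a1, Cyp51, Cyp7a1, Cyp26a1, Cyp2c11, Por, Abcb1a and Abcc3, and some other fixed genes and list members are not reported here. No gene is named from a probe set with several genes. The probe set drawn in the figures beside the fixed genes is assigned to several genes, fixed genes among them, and is given by its ID. Values given for other list members and for probe sets without a single gene were chosen after their values were seen.

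The overlap of responses to different compounds was set against 100 simulations of unchanged groups sharing the control arrays and, for counts, against independent lists. Alternatives were median centring, no filter or a 50% filter on dim probe sets, other variance models, array weights, only the arrays compared, the replicate number as a block, no moderation, the mean of a gene's probe sets, and leaving out each array. Added after the data were seen were the deposited values without normalization, the mean 3' minus 5' difference of GAPDH and beta-actin as a covariate, and comparisons of the other groups without myclobutanil replicate 01.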

Results

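The series measured liver gene expression in adult male Sprague-Dawley rats given 1 of 3 triazole fungicides by gavage. Triazoles block fungal sterol demethylase, the fungal form of Cyp51. All 3 compounds carry a triazole ring: myclobutanil also has a nitrile and a butyl chain, propiconazole a dioxolane ring, and triadimefon a ketone and a phenoxy ether. The rats were 10 weeks old and were dosed every 24 h over 72 h with myclobutanil at 300 mg/kg/day, propiconazole at 300 mg/kg/day or triadimefon at 175 mg/kg/day. Each of the 3 treated groups and the control group held 3 rats, and each liver had its own Affymetrix Rat Genome 230 2.0 array, which gave 12 arrays. The design asks how each compound changed the liver transcriptome against control and how the compounds differed from each other, with a lower dose for triadimefon. What the control rats were given is not stated in the labels.

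Values are the deposited log-like scores after quantile normalization. The base of the logarithm is not stated, so differences are in these log-like units and are not fold changes. As a yardstick, the hybridization spike-ins cre and bioB, added at very different amounts, lay 2.73 units apart in the median array (range 2.42 to 3.39). A difference is given ± SE from limma over 3 arrays per group, and the median 95% interval over all probe sets reached 0.141 units to either side. The number of arrays limits this precision. The array of myclobutanil replicate 01 stood apart from the other arrays: its deposited median was 0.157 against 0.0182 to 0.0552 on the other 11, and its median correlation with the other arrays was 0.927 against 0.962 to 0.982. The GAPDH 3' minus 5' difference, a sign of RNA quality, was 0.659 ± 0.252 (SD, n = 3) in control, 0.624 ± 0.128 in myclobutanil, 0.434 ± 0.106 in propiconazole and 0.587 ± 0.212 in triadimefon. The same difference for beta-actin was 0.682 ± 0.202, 0.807 ± 0.145, 0.636 ± 0.0925 and 0.838 ± 0.200.

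In the liver of rats given myclobutanil, genes of drug metabolism rose and genes of resident macrophages fell against control. The glutathione transferase gene Gsta3 rose by 1.73 ± 0.18, the carboxylesterase gene Ces2c by 1.17 ± 0.18, the glucuronosyltransferase gene Ugt2b1 by 1.12 ± 0.15 and Aldh1a1, which oxidizes retinaldehyde, by 1.0 ± 0.14 (limma adjusted p = 0.00358, 0.0118, 0.0113 and 0.0115, n = 3 arrays per group). Clec4f, a lectin of rodent Kupffer cells, fell by 1.35 ± 0.22, Cd5l, secreted by tissue macrophages, by 1.32 ± 0.28, and the complement gene C1qa by 1.0 ± 0.16 (limma adjusted p = 0.0175, 0.0417 and 0.0133). The deepest fall of a named gene was that of Stac3, an adaptor best known from skeletal muscle calcium release, at 2.39 ± 0.25 (limma adjusted p = 0.00358). In each of these genes all 3 treated arrays lay on the same side of all 3 control arrays.

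Among the 10 largest rises were also Wfdc21 (1.68 ± 0.25), the interferon-induced chemokine gene Cxcl9 (1.13 ± 0.15), the squalene epoxidase gene Sqle of cholesterol synthesis (1.03 ± 0.19), the phosphate transporter gene Slc20a1 (1.02 ± 0.22), the fatty acid binding protein gene Fabp5 (0.99 ± 0.21) and Rell1 (0.99 ± 0.19). The 10 largest falls included Dhrs7l1, a short-chain dehydrogenase gene, by 1.45 ± 0.25, the glycine methyltransferase gene Gnmt by 1.31 ± 0.18, Ppp1r3b, which targets a phosphatase to glycogen, by 1.17 ± 0.24, Nrep by 1.06 ± 0.20, the collagen cross-linking enzyme gene Lox by 1.01 ± 0.17 and the organic anion transporter gene Slc22a8 by 1.01 ± 0.21. Their limma adjusted p ran from 0.00884 for Cxcl9 to 0.044 for Slc20a1. Gsta3, Ces2c, Ugt2b1, Aldh1a1, Cyp3a23-3a1, Cyp1a1, Cyp2c11 and Cyp4a1 have close paralogs, so their probe sets may also read related genes and their values are uncertain in that respect, here and for the other compounds. Among probe sets with no single gene assigned, 1368718_at rose by 2.40 ± 0.26 and 1371076_at, assigned to more than 1 gene, by 2.11 ± 0.17, while 1370725_a_at fell by 1.42 ± 0.19 and 1379888_at by 1.15 ± 0.24 (limma adjusted p = 0.00359, 0.000748, 0.00987 and 0.0403).

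Of the 29 measured CAR and PXR target genes of drug metabolism, 7 rose and none fell in limma (4 lower at an unadjusted p under 0.05). With p adjusted over the list alone, 12 rose and 3 fell. They included Cyp3a23-3a1, the inducible steroid hydroxylase gene (0.41 ± 0.059), Por, which passes electrons to microsomal P450 enzymes (0.64 ± 0.13), and the efflux transporter gene Abcc3 (0.69 ± 0.11). The list stood higher than the other genes (camera adjusted p = 4.23e-06, adjusted p = 0.248 with an estimated correlation). Of 16 NRF2 target genes, the quinone reductase gene Nqo1 (0.70 ± 0.10) and the glutathione reductase gene Gsr (0.33 ± 0.068) rose, 14 did not pass. When adjusted over the list alone, 6 rose and 0 fell. Camera called the list higher (camera adjusted p = 0.0002, adjusted p = 0.248 with an estimated correlation). Nqo1 and Cyp1a1 (0.79 ± 0.18, limma adjusted p = 0.0492), a P450 gene induced through the dioxin receptor AhR, were the 2 of 6 AhR target genes that rose, while Cyp1a2 stood at -0.43 ± 0.14. The AhR list was not called (camera adjusted p = 0.366), and its median of -0.016 and mean of 0.16 differed in sign. Of 20 cholesterol synthesis genes, Sqle and the acetoacetyl-CoA thiolase gene Acat2 (0.67 ± 0.14) rose and none fell in limma (0 lower at an unadjusted p under 0.05). Adjusted over the list alone, 6 rose and 0 fell, and 18 of the 20 differences were above 0. The cholesterol list was called higher (camera adjusted p = 5.96e-05, adjusted p = 0.298 with an estimated correlation). Cyp51, the mammalian form of the fungal target, stood at 0.63 ± 0.15 (limma adjusted p = 0.0634).

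Cell cycle genes were higher as a list (camera adjusted p = 1.96e-13, adjusted p = 0.248 with an estimated correlation). Of 30 measured, 7 rose, 23 did not pass, none fell in limma (1 lower at an unadjusted p under 0.05). In limma adjusted over the list alone, 21 rose and 1 fell. The mitotic kinase gene Cdk1 rose by 0.70 ± 0.14, the proliferation marker Mki67 by 0.30 ± 0.049, the cyclin gene Ccnb1 by 0.31 ± 0.055 and the thymidylate synthase gene Tyms by 0.19 ± 0.035.

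Of 13 Kupffer cell and macrophage markers, 5 fell (Clec4f, Cd5l, C1qa, C1qc by 0.73 ± 0.14 and Adgre1 by 0.30 ± 0.063), 8 did not pass and none rose in limma (0 higher at an unadjusted p under 0.05). With p adjusted over the list alone, 0 rose and 8 fell. The list was called lower (camera adjusted p = 3.92e-05, adjusted p = 0.265 with an estimated correlation). Its mean difference was -0.50, and -0.65 without myclobutanil replicate 01. Other macrophage genes did not pass: the general myeloid genes Cd14 and Lyz2 stood at 0.084 ± 0.13 and 0.27 ± 0.19. Among 19 hepatocyte markers the ethanol-inducible Cyp2e1 fell by 0.59 ± 0.11 and 18 did not pass, with 1 higher and 5 lower adjusted over the list alone. The hepatocyte list was called lower (camera adjusted p = 0.0113, adjusted p = 0.298 with an estimated correlation). Of 18 genes of glucose metabolism, Ppp1r3b, the gluconeogenic Fbp1 (-0.37 ± 0.069) and the pyruvate carboxylase gene Pc (-0.64 ± 0.13) fell, 15 did not pass. If adjusted over the list alone, 0 rose and 7 fell. As a list they were called lower (camera adjusted p = 0.00469, adjusted p = 0.248 with an estimated correlation). In the bile acid list the only member of 20 past the test was Nr0b2, a repressor of bile acid synthesis genes, which fell by 0.88 ± 0.15, while Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at -0.29 ± 0.47. Adjusted over the list alone 0 rose and 2 fell. In camera the list was called lower (camera adjusted p = 0.0135, adjusted p = 0.248 with an estimated correlation). None of the 15 male-biased genes passed limma over all probe sets (1 higher and 4 lower at an unadjusted p under 0.05). In limma adjusted over the list alone, 0 rose and 3 fell. Igf1 stood at -0.36 ± 0.087, Rgn at -0.87 ± 0.22 and the male-specific Cyp2c11 at -0.40 ± 0.23. Together they were called lower as a list (camera adjusted p = 0.0139, adjusted p = 0.407 with an estimated correlation). None of 16 leukocyte markers passed limma (1 higher and 5 lower at an unadjusted p under 0.05). When adjusted over the list alone, 0 rose and 1 fell. The list as a whole was called lower (camera adjusted p = 0.0313, adjusted p = 0.265 with an estimated correlation). Prf1 stood at -0.15 ± 0.038 and S100a9 at 0.59 ± 0.19.

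In the lists camera did not call for myclobutanil, Srd5a3 (0.22 ± 0.043) rose among the steroid genes. Among the retinoid genes Aldh1a1 rose, and the retinol dehydrogenase gene Rdh7 (0.69 ± 0.15) and Lrat, which makes retinyl esters (0.36 ± 0.069), fell by those amounts. Among the thyroid genes Ugt2b1 rose and the sulfotransferase gene Sult1c2 fell by 0.55 ± 0.11, the clock activator gene Npas2 by 0.42 ± 0.091 and the endothelial growth factor receptor gene Kdr by 0.55 ± 0.11. Values that did not pass included the retinoic acid hydroxylase gene Cyp26a1 (0.53 ± 0.12), the efflux transporter gene Abcb1a (0.60 ± 0.16), the PPAR-alpha target Cyp4a1 (-0.088 ± 0.10) and the secreted lipocalin gene Lcn2 (2.13 ± 0.60). Eci1 stood at 0.42 ± 0.11 among the fatty acid oxidation genes, Elovl6 at 0.37 ± 0.12 among the fatty acid synthesis genes, Ccng1 at 0.30 ± 0.09 among the p53 genes, Sdf2l1 at 0.50 ± 0.13 among the ER stress genes and Dusp1 at -0.81 ± 0.39 among the immediate early genes. The camera adjusted p of these lists was 0.348 for steroid, 0.26 for retinoid, 0.714 for thyroid, 0.74 for clock, 0.257 for endothelial, 0.74 for fatty acid oxidation, 0.713 for fatty acid synthesis, 0.369 for p53, 0.0862 for ER stress, 0.428 for immediate early and 0.369 for acute phase genes. Fry called the endothelial list lower (fry adjusted p = 0.00862). Past limma, with list-alone counts in parentheses, were 1 higher and 0 lower of 21 steroid genes (1, 0), 1 higher and 2 lower of 24 retinoid genes (3, 3), 1 higher and 1 lower of 16 thyroid genes (2, 1), 0 higher and 1 lower of 16 clock genes (0, 1), 0 higher and 1 lower of 14 endothelial genes (0, 3) and 0 higher and 1 lower of 14 stellate cell genes (0, 1). No gene passed for fatty acid oxidation (4 higher, 4 lower), fatty acid synthesis (2, 2), p53 (1, 1), ER stress (5, 0), immediate early and heat shock (1, 0) and acute phase (3, 2), where parentheses count an unadjusted p under 0.05. The median and the camera direction differed in sign for the 2 fatty acid lists.

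In total limma called 395 of 21729 probe sets between myclobutanil and control (224 higher, 171 lower), which held 267 genes (151 higher, 116 lower). All 395 had groups that did not overlap. Over all probe sets 23.3% did so, where chance gives 10%. The count was 90, 83 and 30 without control replicates 01, 02 and 03, and 670, 924 and 122 without myclobutanil replicates 01, 02 and 03. Fitting the 6 arrays of the 2 groups alone gave 8 calls (5 higher, 3 lower) and kept 4 of the 43 named calls. Array weights gave 1668 calls (909 higher, 759 lower), no moderation 208 (104 higher, 104 lower) and median centring 324 (161 higher, 163 lower). Of the named genes past the test, 5 of 43 (Cxcl9, Gnmt, Gsta3, Stac3 and Ugt2b1) kept their call whichever array was left out, and Gsr in no such fit. Camera called 10 of 26 lists (4 higher, 6 lower) and none with an estimated correlation (5 at an unadjusted p under 0.05, 10 by fry). It called 6 without myclobutanil replicate 03, which ended the bile acid (camera adjusted p = 0.0759), male-biased (0.165), glucose (0.0542) and hepatocyte (0.0542) calls. The leukocyte call ended without control replicate 02 (0.0959), control replicate 03 (0.155), myclobutanil replicate 02 (0.212) and myclobutanil replicate 03 (0.0586), without the filter on dim probe sets (0.109) and with the deposited values (0.0811) (camera adjusted p in each case). Fry did not call the cholesterol and male-biased lists.

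**Figure D1:**
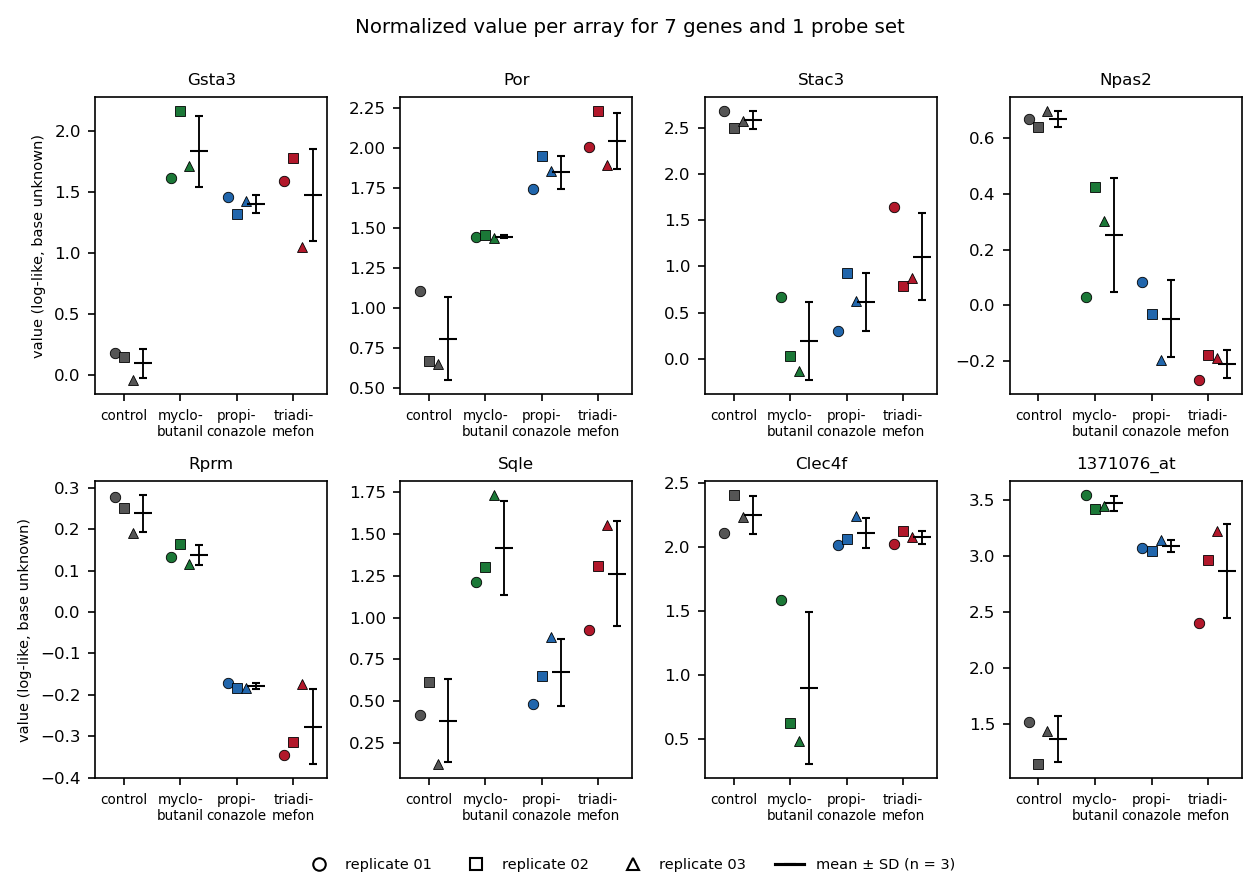
Normalized values (log-like units, base unknown) on each array for 7 genes and the probe set 1371076_at in the 4 groups, with points for arrays and bars for the mean ± SD (n = 3). Gsta3 sat between 1.05 and 2.17 on the treated arrays and between -0.041 and 0.180 on the control arrays, and Clec4f sat between 0.481 and 1.58 on the myclobutanil arrays and between 2.01 and 2.41 on the others.

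In the liver of rats given propiconazole, genes of drug metabolism rose against control. The heme oxygenase gene Hmox1 rose by 1.76 ± 0.29, Ces2c by 1.48 ± 0.18, Gsta3 by 1.30 ± 0.18, Coq10b, a mitochondrial coenzyme Q binding protein gene, by 1.28 ± 0.17 and Por by 1.04 ± 0.13 (limma adjusted p = 0.0199, 0.00582, 0.00954, 0.00682 and 0.00642, n = 3 arrays per group). Stac3 fell by 1.97 ± 0.25, the taurine transporter gene Slc6a6 by 1.28 ± 0.18 and the activin subunit gene Inhba by 1.01 ± 0.11 (limma adjusted p = 0.00661, 0.0113 and 0.00492). All 3 treated arrays lay beyond all 3 control arrays for each of these genes. The GAPDH 3' minus 5' difference averaged 0.434 ± 0.106 (SD, n = 3) in this group against 0.659 ± 0.252 in control.

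The other leading rises were Aldh1a1 (1.13 ± 0.14), Cyp1a1 (0.96 ± 0.18), Ugt2b1 (0.90 ± 0.15), the NAD salvage enzyme gene Nampt (0.89 ± 0.15) and the periplakin gene Ppl (0.85 ± 0.17). The other leading falls were those of Ppp1r3b by 1.19 ± 0.24, Nrep by 1.10 ± 0.20, Lox by 1.0 ± 0.17, Tsc22d1 by 0.97 ± 0.17, the sterol sensor gene Insig2 by 0.88 ± 0.13, the tubulin gene Tubb2a by 0.78 ± 0.14 and the sphingosine phosphate receptor gene S1pr1 by 0.75 ± 0.12. Their limma adjusted p ran from 0.00661 for Aldh1a1 to 0.0406 for Ppl. Among probe sets with no single gene assigned, 1368718_at rose by 2.26 ± 0.26 and 1371076_at by 1.72 ± 0.17, and 1379888_at fell by 1.18 ± 0.24 and 1370420_at by 0.88 ± 0.18 (limma adjusted p = 0.00492, 0.00469, 0.0363 and 0.0377).

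Of the 29 CAR and PXR target genes, 6 rose (Ces2c, Por, Aldh1a1, Gsta3, Ugt2b1 and Cyp3a23-3a1 by 0.34 ± 0.059) and none fell in limma (2 lower at an unadjusted p under 0.05). Adjusted over the list alone 15 rose and 2 fell. The whole list was called higher (camera adjusted p = 3.27e-08, adjusted p = 0.246 with an estimated correlation). Hmox1 was the one NRF2 target gene of 16 that rose, with 5 higher and 0 lower adjusted over the list alone and the list called higher (camera adjusted p = 6.47e-05, adjusted p = 0.246 with an estimated correlation). Cyp1a1 was the one of 6 AhR target genes that rose (limma adjusted p = 0.0278), with 2 higher and 0 lower adjusted over the list alone. The AhR list was not called by camera (camera adjusted p = 0.0706) and was called higher by fry (fry adjusted p = 0.0323), and Cyp1a2 stood at -0.044 ± 0.14. Among 32 genes of fatty acid oxidation and PPAR-alpha targets, the mitochondrial carnitine transferase gene Cpt2 rose by 0.57 ± 0.12, 3 rose and 1 fell adjusted over the list alone. Camera called the list higher (camera adjusted p = 0.00721, adjusted p = 0.543 with an estimated correlation). The PPAR-alpha target Cyp4a1 itself stood at -0.36 ± 0.10.

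The cholesterol and fatty acid synthesis lists were called lower with propiconazole by camera, though not with an estimated correlation. Of 20 cholesterol synthesis genes the sterol dehydrogenase gene Nsdhl fell by 0.42 ± 0.079 and none rose in limma (0 higher at an unadjusted p under 0.05). Adjusted over the list alone 0 rose and 3 fell. In camera the list was called lower (camera adjusted p = 0.0212, adjusted p = 0.628 with an estimated correlation). Cyp51 stood at -0.15 ± 0.15 and Sqle at 0.29 ± 0.19. None of 18 fatty acid synthesis genes passed limma (0 higher and 5 lower at an unadjusted p under 0.05). If adjusted over the list alone, 0 rose and 0 fell. As a list they were called lower (camera adjusted p = 0.0295, adjusted p = 0.628 with an estimated correlation). Srebf1 stood at -0.58 ± 0.21 and Fasn at -0.64 ± 0.26. That call ended with the mean of a gene's probe sets (camera adjusted p = 0.0815). None of 20 bile acid genes passed limma (0 higher and 5 lower at an unadjusted p under 0.05). When adjusted over the list alone, 0 rose and 1 fell. The list as a whole was called lower (camera adjusted p = 0.0127, adjusted p = 0.246 with an estimated correlation). Nr0b2 stood at -0.67 ± 0.15 and Cyp7a1 at -0.038 ± 0.47.

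None of the 30 cell cycle genes passed limma on its own (11 higher and 0 lower at an unadjusted p under 0.05). In limma adjusted over the list alone, 0 rose and 0 fell. The whole list was called higher (camera adjusted p = 1.71e-05, adjusted p = 0.394 with an estimated correlation). Pcna stood at 0.43 ± 0.11. None of 18 immediate early and heat shock genes passed limma either (8 higher and 0 lower at an unadjusted p under 0.05). If adjusted over the list alone, 4 rose and 0 fell. Camera called the list higher (mean 0.429, SE 0.384, adjusted p = 0.017, 0.628 with an estimated correlation). The chaperonin genes Hspe1 stood at 0.45 ± 0.13 and Hspd1 at 0.39 ± 0.12. No acute phase gene of 23 passed limma (4 higher and 1 lower at an unadjusted p under 0.05). When adjusted over the list alone, 0 rose and 0 fell. The list was called higher (mean 0.164, SE 0.121, camera adjusted p = 0.0442, adjusted p = 0.628 with an estimated correlation). Stat3 stood at 0.43 ± 0.14. The acute phase call ended with the 3' minus 5' difference of GAPDH and beta-actin as a covariate (camera adjusted p = 0.146), with the deposited values (0.581) and with the mean of a gene's probe sets (0.079). Of 14 endothelial markers Kdr fell by 0.64 ± 0.11 and the angiopoietin receptor gene Tek by 0.30 ± 0.056, none rose in limma (0 higher at an unadjusted p under 0.05). With p adjusted over the list alone, 0 rose and 2 fell. Together they were called lower as a list (camera adjusted p = 0.0265, adjusted p = 0.246 with an estimated correlation). Kupffer cell markers were not called (camera adjusted p = 0.307): none of 13 passed limma (0 higher and 0 lower at an unadjusted p under 0.05), and Clec4f stood at -0.15 ± 0.22. In the p53 list, not called (camera adjusted p = 0.153), the cyclin gene Ccng1 rose by 0.67 ± 0.09 and Rprm, a mediator of cell cycle arrest, fell by 0.42 ± 0.042 (limma adjusted p = 0.00898 and 0.00469). Past limma, with list-alone counts in parentheses, were 1 higher and 1 lower of 15 p53 genes (3, 2), 1 higher and 1 lower of 24 retinoid genes (2, 1), 1 higher and 0 lower of 16 thyroid genes (1, 0), 0 higher and 1 lower of 14 stellate cell genes (0, 1), 0 higher and 1 lower of 16 clock genes (1, 2), 0 higher and 1 lower of 18 glucose genes (1, 1) and 1 higher and 0 lower of 19 hepatocyte genes (1, 0). No gene passed for male-biased (2 higher, 6 lower), leukocyte (0, 0), steroid (3, 2) and ER stress (4, 2), where parentheses count an unadjusted p under 0.05. List-alone counts there were 2 and 3 for male-biased, and 0 and 0 for the others. Npas2 fell by 0.72 ± 0.091, Lrat by 0.40 ± 0.069 and the apolipoprotein gene Apoa1 rose by 0.49 ± 0.089. Cyp26a1 stood at 0.48 ± 0.12, Abcb1a at 0.21 ± 0.16, Abcc3 at 0.40 ± 0.11, Cyp2c11 at -0.04 ± 0.23, Hsd17b2 at 0.90 ± 0.28 and Trib3 at 0.86 ± 0.30. The camera adjusted p of the uncalled lists was 0.075 for male-biased genes, 0.613 for glucose, 0.99 for clock, 0.822 for hepatocyte and 0.159 for leukocyte genes, and for glucose, clock and hepatocyte genes the mean or median and the camera direction differed in sign.

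In total limma called 311 probe sets between propiconazole and control (176 higher, 135 lower) with 199 genes (118 higher, 81 lower). The groups of all 311 did not overlap, as in 27.8% of all probe sets, where chance gives 10%. The count was 54, 43 and 36 without control replicates 01, 02 and 03, 49, 170 and 46 without propiconazole replicates 01, 02 and 03, and 969 without myclobutanil replicate 01, whose spread enters the fit. The 6 arrays of the 2 groups alone gave 648 calls (399 higher, 249 lower), array weights 1313 (738 higher, 575 lower) and no moderation 162 (78 higher, 84 lower). Of the named genes past the test, 8 of 30 (Aldh1a1, Ces2c, Coq10b, Inhba, Npas2, Por, Rprm and Stac3) kept their call whichever array of the 2 groups was left out. Hmox1 kept it in 1 of these 6 fits, and 7 genes, Nsdhl among them, in none. Camera called 10 of 26 lists (6 higher, 4 lower) and none with an estimated correlation (4 at an unadjusted p under 0.05, 5 by fry). By camera adjusted p, calls ended for fatty acid oxidation genes without propiconazole replicate 02 (0.112), for cholesterol genes without control replicate 01 (0.07), control replicate 02 (0.0898) and propiconazole replicate 01 (0.106) and for fatty acid synthesis genes without control replicate 01 (0.229), propiconazole replicate 01 (0.283) and myclobutanil replicate 01 (0.0554). They ended for acute phase genes without control replicate 02 (0.0549), control replicate 03 (0.121), propiconazole replicate 02 (0.0616) and propiconazole replicate 03 (0.0989), for heat shock genes without control replicate 01 (0.229) and propiconazole replicate 03 (0.104) and for endothelial genes without control replicate 02 (0.0984) (camera adjusted p in each case). Fry did not call the fatty acid oxidation, cholesterol, fatty acid synthesis, cell cycle, acute phase and heat shock lists.

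In the liver of rats given triadimefon, at the lower dose of 175 mg/kg/day, genes of drug metabolism rose and genes of the circadian clock changed against control. Clock genes follow the hour of the day, and the labels give no hour of sampling for each animal. Coq10b rose by 1.47 ± 0.17, Gsta3 by 1.38 ± 0.18, Por by 1.24 ± 0.13 and Dbp, a transcription factor driven by the clock, by 1.21 ± 0.16 (limma adjusted p = 0.00711, 0.0101, 0.00477 and 0.0107, n = 3 arrays per group). Npas2 and Bmal1, activators of the clock, fell by 0.88 ± 0.091 and 0.68 ± 0.094, and Dhrs7l1 and Stac3 fell by 1.57 ± 0.25 and 1.48 ± 0.25 (limma adjusted p = 0.00477, 0.0122, 0.016 and 0.022). All 3 treated arrays lay beyond all 3 control arrays for each of these genes.

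The other leading rises were Slc20a1 (1.26 ± 0.22), Ces2c (1.19 ± 0.18), Rell1 (1.12 ± 0.19), Aldh1a1 (0.93 ± 0.14), Ugt2b1 (0.91 ± 0.15) and the phosphatidate phosphatase gene Lpin2 (0.85 ± 0.13). Leading falls were those of Slc6a6 by 1.24 ± 0.18, Insig2 by 1.13 ± 0.13, Inhba by 1.0 ± 0.11, the sulfate transporter gene Slc13a4 by 0.79 ± 0.10, the glycerol kinase gene Gk by 0.78 ± 0.11, the olfactory receptor gene Olr59 by 0.73 ± 0.094 and the tight junction gene Cldn1 by 0.72 ± 0.066. Their limma adjusted p ran from 0.00271 for Cldn1 to 0.0238 for Slc20a1. Among probe sets with no single gene assigned, 1368718_at rose by 1.78 ± 0.26 and 1371076_at by 1.5 ± 0.17, and 1387902_a_at fell by 0.90 ± 0.12 and 1372452_at by 0.82 ± 0.13 (limma adjusted p = 0.0122, 0.00711, 0.0107 and 0.0186).

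Of the 29 CAR and PXR target genes, 6 rose (Por, Gsta3, Ces2c, Aldh1a1, Ugt2b1 and Cyp3a23-3a1 by 0.41 ± 0.059) and none fell in limma (0 lower at an unadjusted p under 0.05). With p adjusted over the list alone, 8 rose and 0 fell. The list as a whole was called higher (camera adjusted p = 1.35e-09, adjusted p = 0.187 with an estimated correlation). Of 16 clock genes, Dbp and Per3 (0.30 ± 0.037) rose and Npas2 and Bmal1 fell, 5 rose and 2 fell adjusted over the list alone. As a list they were called higher (camera adjusted p = 0.045, adjusted p = 0.437 with an estimated correlation). The clock call ended with the deposited values (camera adjusted p = 0.0534). Per2 stood at 0.92 ± 0.21 and Nr1d2 at 0.56 ± 0.20. Of 16 NRF2 target genes none passed limma (4 higher and 0 lower at an unadjusted p under 0.05). In limma adjusted over the list alone, 2 rose and 0 fell. In camera the list was called higher (camera adjusted p = 0.0231, adjusted p = 0.56 with an estimated correlation). The sulfiredoxin gene Srxn1 stood at 1.24 ± 0.33 and Hmox1 at 1.0 ± 0.29. The NRF2 call ended with the deposited values (camera adjusted p = 0.0947). None of 20 cholesterol synthesis genes passed limma (5 higher and 1 lower at an unadjusted p under 0.05). If adjusted over the list alone, 2 rose and 0 fell. Together they were called higher as a list (camera adjusted p = 0.00335, adjusted p = 0.56 with an estimated correlation). Sqle stood at 0.88 ± 0.19, Acat2 at 0.58 ± 0.14 and Cyp51 at 0.39 ± 0.15. None of 30 cell cycle genes passed limma (5 higher and 0 lower at an unadjusted p under 0.05). When adjusted over the list alone, 0 rose and 0 fell. The whole list was called higher (camera adjusted p = 0.00119, adjusted p = 0.56 with an estimated correlation). Mcm4 stood at 0.17 ± 0.043. Likewise none of 18 immediate early and heat shock genes passed limma (5 higher and 0 lower at an unadjusted p under 0.05). With p adjusted over the list alone, 0 rose and 0 fell. Camera called the list higher (mean 0.537, SE 0.384, adjusted p = 0.00119, 0.719 with an estimated correlation). The chaperone genes Dnaja1 stood at 0.59 ± 0.19 and Hspa1a at 1.81 ± 0.61.

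In the p53 list, not called (camera adjusted p = 0.492), Ccng1 rose by 0.52 ± 0.09 and Rprm fell by 0.52 ± 0.042. None of 6 AhR target genes passed limma (2 higher and 0 lower at an unadjusted p under 0.05), with Cyp1a1 at 0.43 ± 0.18 and Cyp1a2 at -0.27 ± 0.14, and none of 13 Kupffer cell markers did (0 higher and 0 lower), with Clec4f at -0.18 ± 0.22. Past limma, with list-alone counts in parentheses, were 1 higher and 1 lower of 15 p53 genes (1, 1), 1 higher and 0 lower of 24 retinoid genes (2, 1) and 1 higher and 0 lower of 16 thyroid genes (2, 1). No gene passed for stellate cell (1 higher, 1 lower), fatty acid oxidation (0, 1), fatty acid synthesis (3, 1), bile acid (2, 3), male-biased (1, 1), glucose (2, 5), acute phase (1, 1), hepatocyte (2, 0), endothelial (0, 2), leukocyte (0, 1), steroid (2, 3) and ER stress (4, 1), where parentheses count an unadjusted p under 0.05. List-alone counts there were 0 and 1 for stellate cell, 0 and 1 for bile acid, 1 and 0 for male-biased, 1 and 2 for glucose, 1 and 0 for steroid, and 0 and 0 for the others. Cyp7a1 stood at 0.95 ± 0.47, Cyp26a1 at 0.58 ± 0.12, Cyp4a1 at -0.36 ± 0.10, Cyp2c11 at -0.042 ± 0.23, Abcb1a at 0.45 ± 0.16 and Abcc3 at 0.45 ± 0.11. Hsd17b2 stood at 1.19 ± 0.28, Lox at -0.82 ± 0.17, Acss2 at 0.60 ± 0.19, Nr0b2 at -0.61 ± 0.15, Fbp1 at -0.31 ± 0.069 and Kdr at -0.41 ± 0.11, none past limma. The camera adjusted p was 0.492 for the AhR, 0.608 for the Kupffer cell, 0.645 for the fatty acid oxidation, 0.102 for the fatty acid synthesis and 0.609 for the bile acid list. The camera adjusted p was 0.721 for the male-biased, 1 for the glucose, 0.704 for the acute phase, 0.492 for the hepatocyte, 0.492 for the endothelial and 0.0652 for the leukocyte list. The mean and the camera direction differed in sign for the glucose list, and the median and mean for the acute phase list.

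In total limma called 167 probe sets between triadimefon and control (106 higher, 61 lower) with 99 genes (66 higher, 33 lower). The groups of all 167 did not overlap, as in 28.3% of all probe sets, where chance gives 10%. The count was 10, 58 and 15 without control replicates 01, 02 and 03, 60, 6 and 51 without triadimefon replicates 01, 02 and 03, and 611 without myclobutanil replicate 01. It was 621 (468 higher, 153 lower) for the 6 arrays of the 2 groups alone, 1028 (588 higher, 440 lower) with array weights and 62 (28 higher, 34 lower) without moderation. Of the named genes past the test, 5 of 25 (Cldn1, Coq10b, Npas2, Por and Rprm) kept their call whichever array of the 2 groups was left out, and Rell1 and Slc20a1 in no such fit. Camera called 6 of 26 lists, all higher, and none with an estimated correlation (2 at an unadjusted p under 0.05, 1 by fry), 10 without triadimefon replicate 01 and 3 without triadimefon replicate 02. By camera adjusted p, calls ended for NRF2 genes without control replicate 02 (0.13) and triadimefon replicate 02 (0.157), for cholesterol genes without triadimefon replicate 03 (0.174) and for heat shock genes without triadimefon replicate 02 (0.157). Clock genes lost their call without control replicate 02 (0.0687), control replicate 03 (0.0672), triadimefon replicate 02 (0.187) and triadimefon replicate 03 (0.0628) (camera adjusted p in each case). Fry did not call the NRF2, cholesterol, cell cycle, clock and heat shock lists.

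Camera called several lists for none of the compounds against control. In the order myclobutanil, propiconazole and triadimefon, the mean difference was -0.13, -0.022 and -0.039 for steroid hormone metabolism (camera adjusted p = 0.348, 0.822 and 0.492), -0.05, 0.012 and -0.0077 for retinoid metabolism (camera adjusted p = 0.26, 0.437 and 0.492). It was -0.025, 0.06 and 0.11 for thyroid hormone metabolism (camera adjusted p = 0.714, 0.437 and 0.247). Among ER stress genes the mean was 0.16, 0.15 and 0.18 (camera adjusted p = 0.0862, 0.437 and 0.262). The other cell type lists had means of -0.033, -0.077 and 0.074 for stellate cells and fibroblasts (camera adjusted p = 0.724, 0.527 and 0.307) and 0.18, 0.20 and 0.21 for cholangiocytes (camera adjusted p = 0.288, 0.132 and 0.0871). They had means of -0.13, -0.0035 and -0.044 for blood (camera adjusted p = 0.265, 0.675 and 0.492) and -0.075, -0.036 and -0.065 for pancreas (camera adjusted p = 0.105, 0.257 and 0.169). Of these lists fry called that of the pancreas lower with myclobutanil (fry adjusted p = 0.0219). Epcam of the cholangiocyte list stood at 0.42 ± 0.15, 0.52 ± 0.15 and 0.39 ± 0.15, Slc4a1 of the blood list at -0.087 ± 0.039, -0.064 ± 0.039 and -0.056 ± 0.039, and Cela1 of the pancreas list at -0.30 ± 0.11, -0.17 ± 0.11 and -0.35 ± 0.11. The mean and the camera direction differed in sign for retinoid metabolism with propiconazole.

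**Figure D2:**
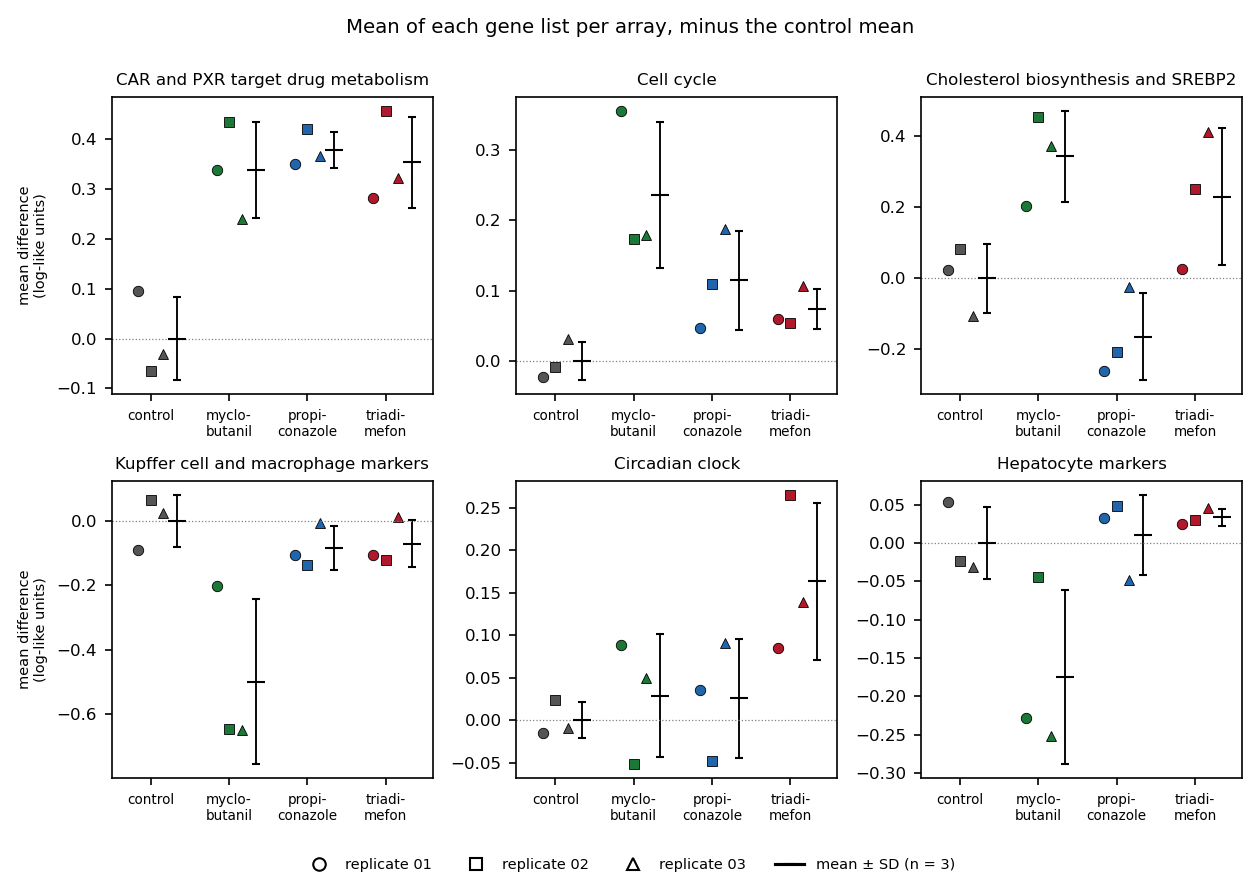
Mean of 6 gene lists on each array minus the control mean (log-like units), with points for arrays and bars for the mean ± SD (n = 3) in the 4 groups. Kupffer cell markers averaged -0.50 with myclobutanil, -0.084 with propiconazole and -0.071 with triadimefon, and cholesterol synthesis genes 0.34, -0.16 and 0.23.

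Myclobutanil and propiconazole, both given at 300 mg/kg/day, differed in cholesterol synthesis genes and Kupffer cell markers, among others, as lists by camera (adjusted p = 0.231 and 0.304 with an estimated correlation). All 20 cholesterol synthesis genes had a higher mean with myclobutanil, with the squalene synthase gene Fdft1 0.77 ± 0.12 and Cyp51 0.78 ± 0.15 higher (limma adjusted p = 0.0779 and 0.175, n = 3 arrays per group). None of the 20 passed limma over all probe sets (14 higher and 0 lower at an unadjusted p under 0.05). Adjusted over the list alone 13 were higher and 0 lower. Camera called the list higher (mean 0.508, SE 0.115, adjusted p = 1.19e-15). Kupffer cell markers were called lower with myclobutanil (mean -0.416, SE 0.117, camera adjusted p = 9.70e-06). C1qa differed by -0.86 ± 0.16 and Clec4f by -1.21 ± 0.22, none of 13 passed limma (0 higher and 8 lower at an unadjusted p under 0.05), and adjusted over the list alone 0 were higher and 8 lower.

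The cell cycle list was called higher with myclobutanil (camera adjusted p = 2.65e-07, adjusted p = 0.304 with an estimated correlation). None of the 30 members passed limma (11 higher and 0 lower at an unadjusted p under 0.05), and adjusted over the list alone 0 were higher and 0 lower. Mki67 stood at 0.18 ± 0.049. Hepatocyte markers were called lower (camera adjusted p = 0.000105, adjusted p = 0.284 with an estimated correlation). None of the 19 members passed limma (0 higher and 5 lower at an unadjusted p under 0.05), and adjusted over the list alone 0 were higher and 0 lower. Ass1 stood at -0.45 ± 0.12. Glucose metabolism was called lower (camera adjusted p = 0.00151, adjusted p = 0.284 with an estimated correlation). None of the 18 members passed limma (0 higher and 6 lower at an unadjusted p under 0.05), and adjusted over the list alone 0 were higher and 5 lower. The serine dehydratase gene Sds stood at -1.20 ± 0.34. Fatty acid oxidation genes were called lower (camera adjusted p = 0.00325, adjusted p = 0.691 with an estimated correlation). None of the 32 members passed limma (2 higher and 5 lower at an unadjusted p under 0.05), and adjusted over the list alone 0 were higher and 0 lower. Cpt2 stood at -0.37 ± 0.12. Fatty acid synthesis genes were called higher (camera adjusted p = 0.00325, adjusted p = 0.717 with an estimated correlation). None of the 18 members passed limma (6 higher and 0 lower at an unadjusted p under 0.05), and adjusted over the list alone 2 were higher and 0 lower. Fasn stood at 0.93 ± 0.26.

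The 95% interval of the difference between myclobutanil and propiconazole was -0.065 to 0.20 for Cyp3a23-3a1, -0.55 to 0.22 for Cyp1a1, -0.22 to 0.31 for Cyp26a1, -0.87 to 0.15 for Cyp2c11 and -1.29 to 0.78 for Cyp7a1, which all include 0. It was -0.68 to -0.12 for Por, -0.69 to -0.088 for Cyp1a2, 0.05 to 0.49 for Cyp4a1, 0.036 to 0.73 for Abcb1a and 0.061 to 0.53 for Abcc3, and 0.011 to 0.76 for 1371076_at, none past limma after adjustment. Limma called 0 probe sets (2200 at an unadjusted p under 0.05, smallest adjusted p 0.0586), and non-overlapping groups made up 13.4%, where chance gives 10%. The count was 29, 9 and 1 without myclobutanil replicates 01, 02 and 03 and 2 without propiconazole replicate 03. By camera adjusted p, list calls ended for fatty acid oxidation genes without myclobutanil replicate 01 (0.0887) and propiconazole replicate 02 (0.114), for fatty acid synthesis genes without myclobutanil replicate 01 (0.134), myclobutanil replicate 02 (0.24) and propiconazole replicate 01 (0.182) and for glucose genes without myclobutanil replicate 03 (0.11). Camera called 7 of 26 lists and none with an estimated correlation (3 at an unadjusted p under 0.05, 1 by fry). Of the called lists fry called that of cholesterol synthesis.

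Between myclobutanil at 300 and triadimefon at 175 mg/kg/day, a few genes differed past limma's test, the clock genes Dbp, Per3 and Nr1d2 and Rprm among them. Dbp was lower with myclobutanil, at a difference of -1.18 ± 0.16, and its difference to control was 0.024 with myclobutanil and 1.21 with triadimefon. Per3 (-0.29 ± 0.037), Nr1d2 (-0.64 ± 0.09) and Fcna (-0.64 ± 0.083), a lectin of the complement system, were also lower. Rprm (0.41 ± 0.042) and the serum amyloid gene Saa3 (0.40 ± 0.052) were higher (limma adjusted p = 0.0471, 0.0471, 0.0471, 0.0471, 0.0152 and 0.0471 in this order, n = 3 arrays per group). The value of Nr1d2 is that of a second probe set, named after it was seen, and the probe set counted in the clock list stood at -0.44 ± 0.20 and did not pass. Of 16 clock genes, 2 were lower in limma, 14 did not pass and none was higher (3 higher at an unadjusted p under 0.05), and adjusted over the list alone 3 were higher and 6 lower. The clock list was not called (camera adjusted p = 0.0982, adjusted p = 0.312 with an estimated correlation), and the activators Bmal1 and Npas2 stood at 0.55 ± 0.094 and 0.46 ± 0.091. The hour of sampling of each animal is not given in the labels.

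Kupffer cell markers were called lower with myclobutanil than with triadimefon (camera adjusted p = 1.49e-07, adjusted p = 0.168 with an estimated correlation). None of the 13 members passed limma (0 higher and 8 lower at an unadjusted p under 0.05), and adjusted over the list alone 0 were higher and 8 lower. Adgre1 stood at -0.37 ± 0.063. Cell cycle genes were called higher (camera adjusted p = 2.64e-11, adjusted p = 0.168 with an estimated correlation). None of the 30 members passed limma (17 higher and 1 lower at an unadjusted p under 0.05), and adjusted over the list alone 14 were higher and 0 lower. Ccnb1 stood at 0.26 ± 0.055. Hepatocyte markers and glucose genes were called lower (camera adjusted p = 1.98e-06 and 3.69e-05, both 0.168 with an estimated correlation). Of 19 and 18 members none passed limma (0 and 0 higher, 10 and 7 lower at an unadjusted p under 0.05), and adjusted over the list alone 1 and 4 were lower, with Cyp2e1 at -0.43 ± 0.11 and Ugp2 at -0.40 ± 0.091. Male-biased and bile acid genes were called lower (camera adjusted p = 0.00388 for both, 0.422 and 0.168 with an estimated correlation). Hsd17b2, which oxidizes testosterone and estradiol, stood at -1.71 ± 0.28 (limma adjusted p = 0.0812). Cyp7a1 stood at -1.25 ± 0.47. In these lists of 15 and 20 genes none passed limma (0 and 0 higher, 2 and 2 lower at an unadjusted p under 0.05), and adjusted over the list alone 1 and 0 were lower.

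NRF2 target and cholesterol synthesis genes were called higher with myclobutanil than with triadimefon. Their camera adjusted p was 0.0276 and 0.0484 (0.501 and 0.663 with an estimated correlation). Their means were 0.103 and 0.113 (SE over arrays 0.113 and 0.115). Immediate early and heat shock genes were called lower (mean -0.428, SE 0.384, camera adjusted p = 0.004, 0.663 with an estimated correlation). The NRF2 call ended without the filter on dim probe sets (0.0563) and with the deposited values (0.104). The cholesterol call ended without that filter (0.0563), with the deposited values (0.364) and with the mean of a gene's probe sets (0.06, camera adjusted p in each case). Gsr stood at 0.32 ± 0.068, Fdft1 at 0.43 ± 0.12 and Egr1 at -1.09 ± 0.52. None of their 16, 20 and 18 members passed limma (3, 2 and 0 higher and 0, 1 and 1 lower at an unadjusted p under 0.05), and adjusted over the list alone 2 NRF2 target genes were higher. The 95% interval was -0.88 to -0.32 for Por, 0.048 to 0.49 for Cyp4a1, -2.28 to -0.21 for Cyp7a1 and 0.23 to 0.99 for 1371076_at, none past limma after adjustment. It was -0.13 to 0.13 for Cyp3a23-3a1, -0.025 to 0.74 for Cyp1a1, -0.47 to 0.13 for Cyp1a2, -0.088 to 0.58 for Cyp51, -0.32 to 0.21 for Cyp26a1, -0.87 to 0.15 for Cyp2c11, -0.20 to 0.50 for Abcb1a and 0.0059 to 0.48 for Abcc3. Limma called 6 probe sets (2 higher, 4 lower; 1653 at an unadjusted p under 0.05), and non-overlapping groups made up 10.9%, where chance gives 10%. The count was 35, 23 and 3 without myclobutanil replicates 01, 02 and 03, 0, 0 and 1 without triadimefon replicates 01, 02 and 03 (1420, 1208 and 1125 at an unadjusted p under 0.05), and 9 (5 higher, 4 lower) for the deposited values. Other fits gave 0 to 340 calls, as listed further below. Camera called 9 of 26 lists and none with an estimated correlation (5 at an unadjusted p under 0.05, 4 by fry), 14 without myclobutanil replicate 01 and 6 without myclobutanil replicate 03. By camera adjusted p, calls ended for NRF2 genes without myclobutanil replicate 01 (0.174) and triadimefon replicate 01 (0.348), for cholesterol genes without myclobutanil replicate 02 (0.547), myclobutanil replicate 03 (0.135) and triadimefon replicate 01 (0.827) and for bile acid genes without myclobutanil replicate 03 (0.0723). They ended for male-biased genes without myclobutanil replicate 03 (0.244) and triadimefon replicate 01 (0.0744) and for heat shock genes without myclobutanil replicate 02 (0.242), myclobutanil replicate 03 (0.0867) and triadimefon replicate 02 (0.4) (camera adjusted p in each case). Fry did not call these lists either.

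Between propiconazole at 300 and triadimefon at 175 mg/kg/day, genes of sterol and fatty acid synthesis lay lower with propiconazole and genes of fatty acid oxidation higher, as lists by camera (adjusted p = 0.0655, 0.214 and 0.116 with an estimated correlation). All 20 cholesterol synthesis genes had a lower mean with propiconazole, with the sterol transfer gene Stard4 at -0.42 ± 0.076 and Cyp51 at -0.53 ± 0.15 (n = 3 arrays per group). The list was called lower (mean -0.395, SE 0.115, camera adjusted p = 1.12e-19). Adjusted over the list alone 0 were higher and 8 lower. None passed limma over all probe sets (0 higher and 9 lower at an unadjusted p under 0.05). Fatty acid synthesis genes were called lower (mean -0.362, SE 0.168, camera adjusted p = 9.80e-10). None of the 18 members passed limma (0 higher and 9 lower at an unadjusted p under 0.05), and adjusted over the list alone 0 were higher and 8 lower. Elovl6 stood at -0.50 ± 0.12. Fatty acid oxidation genes were called higher (mean 0.185, SE 0.0584, camera adjusted p = 1.71e-08). None of the 32 members passed limma (6 higher and 1 lower at an unadjusted p under 0.05), and adjusted over the list alone 0 were higher and 0 lower. The lipid droplet gene Plin2 stood at 0.65 ± 0.18. Clock genes were called lower (camera adjusted p = 0.00115, adjusted p = 0.0655 with an estimated correlation). None of the 16 members passed limma (1 higher and 5 lower at an unadjusted p under 0.05), and adjusted over the list alone 1 were higher and 5 lower. Hlf stood at -0.53 ± 0.092.

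Bile acid genes were called lower with propiconazole than with triadimefon (camera adjusted p = 0.00115, adjusted p = 0.105 with an estimated correlation). Abcg5 stood at -0.68 ± 0.19. Endothelial markers were also lower (camera adjusted p = 0.00303, adjusted p = 0.0655 with an estimated correlation). Tek stood at -0.14 ± 0.056. Stellate cell markers (camera adjusted p = 0.00148, adjusted p = 0.4 with an estimated correlation) and male-biased genes (camera adjusted p = 0.0107, adjusted p = 0.48 with an estimated correlation) were called lower, with Reln at -0.34 ± 0.16 and Cyp2a2 at -0.21 ± 0.077. NRF2 target genes (camera adjusted p = 0.00303, adjusted p = 0.315 with an estimated correlation) were called higher, with Hmox1 at 0.76 ± 0.29. So were acute phase genes (camera adjusted p = 0.0057, adjusted p = 0.558 with an estimated correlation) and AhR target genes (camera adjusted p = 0.0194, adjusted p = 0.116 with an estimated correlation). With the 3' minus 5' difference of GAPDH and beta-actin as a covariate the NRF2 (camera adjusted p = 0.0589), acute phase (0.0589) and AhR (0.215) calls ended. The GAPDH 3' minus 5' difference was 0.434 ± 0.106 with propiconazole and 0.587 ± 0.212 with triadimefon (SD, n = 3). The male-biased call ended with the deposited values (camera adjusted p = 0.0789). A2m stood at 1.27 ± 0.49 and Cyp1a1 at 0.53 ± 0.18. In these lists no member passed limma, and at an unadjusted p under 0.05 the members lower were 3 bile acid, 1 endothelial, 0 stellate cell and 3 male-biased genes and the members higher 4 NRF2 target, 1 acute phase and 1 AhR target genes. Adjusted over the list alone, 2 bile acid genes were lower and no member of the others passed.

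The 95% interval of the difference between propiconazole and triadimefon was 0.14 to 0.91 for Cyp1a1 and -0.87 to -0.20 for Cyp51, neither past limma after adjustment. It was -0.20 to 0.061 for Cyp3a23-3a1, -0.48 to 0.082 for Por, -0.079 to 0.52 for Cyp1a2, -0.22 to 0.22 for Cyp4a1, -2.03 to 0.045 for Cyp7a1, -0.36 to 0.17 for Cyp26a1, -0.50 to 0.51 for Cyp2c11, -0.59 to 0.11 for Abcb1a, -0.29 to 0.18 for Abcc3 and -0.15 to 0.60 for 1371076_at, which all include 0. Limma called 0 probe sets (803 at an unadjusted p under 0.05, where chance gives 1086, smallest adjusted p 0.431). It called 45 with array weights and 0 in each other fit run. The unadjusted count was 1622 with the 6 arrays alone and 1510 without myclobutanil replicate 01. It was 2248 with array weights and below 1086 in the other fits. Non-overlapping groups made up 12.8%, where chance gives 10%. Camera called 11 of 26 lists (4 higher, 7 lower) and none with an estimated correlation (6 at an unadjusted p under 0.05, 1 by fry). By camera adjusted p, calls ended for AhR genes without propiconazole replicate 03 (0.0538), triadimefon replicate 01 (0.316) and myclobutanil replicate 01 (0.0561), for NRF2 genes without propiconazole replicate 03 (0.2) and triadimefon replicate 01 (0.198) and for male-biased genes without propiconazole replicate 03 (0.0597) and triadimefon replicate 01 (0.216). They ended for acute phase genes without propiconazole replicate 03 (0.052) and triadimefon replicate 01 (0.109), for clock genes without triadimefon replicate 02 (0.0694) and for stellate cell genes without triadimefon replicate 03 (0.678) (camera adjusted p in each case). Of the called lists fry called that of endothelial markers.

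**Figure D3:**
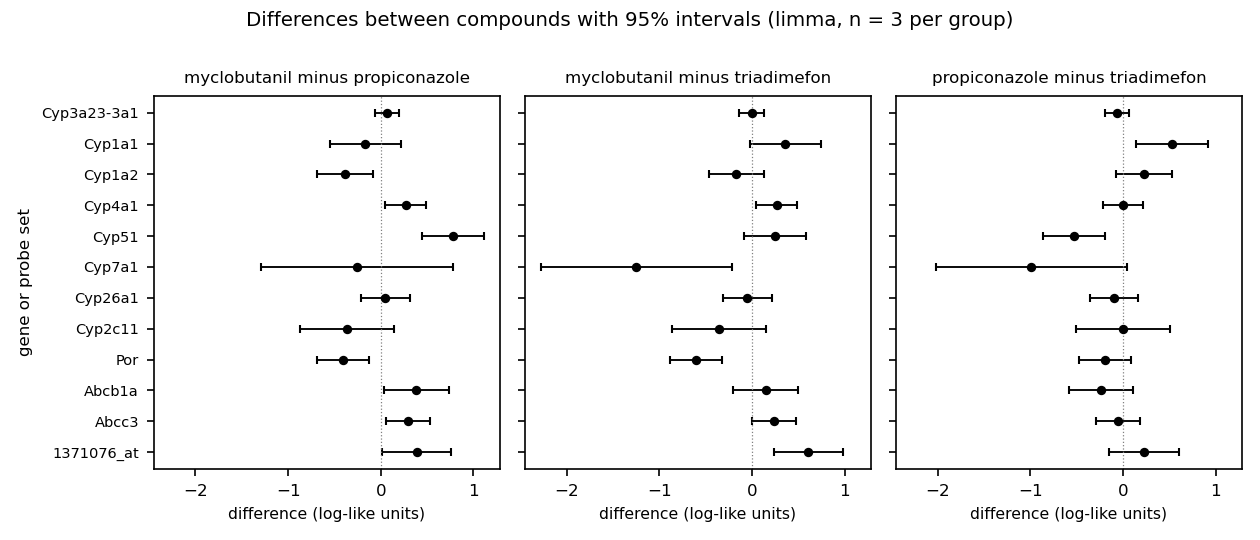
Differences between compounds (log-like units) for fixed genes and the probe set 1371076_at, with points for the difference and bars for the 95% interval from limma (n = 3 per group). The intervals for Cyp3a23-3a1 include 0 in all 3 comparisons, and that for Cyp51 lies above 0 between myclobutanil and propiconazole (0.44 to 1.11).

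The responses to the 3 compounds shared many genes. Limma called 26 genes higher and 17 lower with every compound against control, out of 241 and 165 called with at least 1. In the order myclobutanil, propiconazole and triadimefon, the differences were 1.73, 1.30 and 1.38 for Gsta3, 1.17, 1.48 and 1.19 for Ces2c, 0.86, 1.28 and 1.47 for Coq10b and 0.64, 1.04 and 1.24 for Por. Azin1, which restrains the antizyme of polyamine synthesis, differed by 0.48, 0.69 and 0.72 and the phosphatase gene Ptp4a1 by 0.61, 0.62 and 0.73. Lower with every compound were Stac3 (-2.39, -1.97 and -1.48), Slc6a6 (-0.86, -1.28 and -1.24), Inhba (-0.87, -1.01 and -1.0), Slc13a4 (-0.91, -0.72 and -0.79), Gk (-0.66, -0.52 and -0.78) and Npas2 (-0.42, -0.72 and -0.88).

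Myclobutanil and propiconazole shared 45 genes called higher and 37 called lower, where independent lists would share 1.5 and 0.793. Myclobutanil and triadimefon shared 36 and 20 (independent lists 0.842 and 0.323), and propiconazole and triadimefon 39 and 25 (independent lists 0.658 and 0.226). No gene was called in opposite directions. Across 11842 genes, which are not independent replicates, the differences to control correlated at r = 0.665 (rho = 0.607) for myclobutanil and propiconazole, 0.694 (rho = 0.653) for myclobutanil and triadimefon and 0.802 (rho = 0.755) for propiconazole and triadimefon. Unchanged groups simulated against the same controls gave r = 0.499. The same sign was found in 72.6%, 74.8% and 80.1% of genes, against 66.7% simulated. The covariance was 0.0190, 0.0187 and 0.0194 against 0.00424 simulated, an excess of 0.0147, 0.0145 and 0.0152 with jackknife SE of 0.0051, 0.00337 and 0.00502 over 9 arrays. The 3 control arrays cannot be split into parts of 2 or more, so part of the overlap may come from the shared controls.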

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

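The tests of explanations for the Kupffer cell markers were chosen after the result was seen. The cre spike-in had a 3' minus 5' difference of 0.520 log-like units on myclobutanil replicate 01, where the highest control array had 0.169, and the bioD spike-in one of 0.653, where the highest control array had 0.163. These spike-ins enter no comparison between groups and stood out as a signal outside the main measurement.

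Kupffer cell and macrophage markers averaged -0.499 in myclobutanil against control, and -0.648 (SE 0.0628) without the array just named, which argues against that array as the source. The endothelial, stellate cell and leukocyte lists averaged -0.0949, -0.0332 and -0.0515 and the cholangiocyte list 0.182 (together 0.000547), and camera called the leukocyte list lower (camera adjusted p = 0.0313, adjusted p = 0.265 with an estimated correlation). The Kupffer difference beyond their common mean was -0.50 (SE 0.123), and beyond each list -0.404 (SE 0.115), -0.466 (SE 0.165), -0.448 (SE 0.0979) and -0.681 (SE 0.155) in that order, which argues against a lower share of all non-hepatocyte cells as the whole cause. With the 3' minus 5' difference as a covariate the mean was -0.506 (SE 0.124), which argues against RNA quality as the whole cause. A loss of Kupffer cells or a lower expression per cell with myclobutanil may underlie it, as a hypothesis that bulk tissue cannot divide further.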

How the results depend on the processing

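The deposited values, the covariate fits and the fits of the other comparisons without myclobutanil replicate 01 were chosen after results were seen; all other alternatives were set in advance. No called result changed direction in any alternative. Of 105 counts of called probe sets under alternatives, 48 stayed within 1.5 times and 57 moved further, and of 81 counts of called lists 66 and 15. Some of the 48 held no call in either fit. With any array left out, every count against control moved further. Over 716 values of single called lists, 554 kept their call and 162 lost it. Over 3552 values of named genes, 3044 kept their side of the threshold, 445 lost a call, 54 gained one and 9 moved. Except where the alternative has fewer arrays or a stricter test by construction, the cause was not tested.

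In the order myclobutanil, propiconazole and triadimefon against control, array weights gave 1668, 1313 and 1028 calls (myclobutanil replicate 01 had a weight of 0.0958), the 6 arrays compared alone 8, 648 and 621, and no moderation 208, 162 and 62. Leaving out 1 array gave 30 to 924, 36 to 969 and 6 to 611 calls in this order. Between myclobutanil and propiconazole, with 0 calls by limma (2200 at an unadjusted p under 0.05), array weights gave 343, no intensity trend 5, median centring 1, the 50% filter 2, no moderation 1, the deposited values 1 and leaving out 1 array 0 to 29. Between myclobutanil and triadimefon, with 6 calls by limma, array weights gave 340, no filter 1, the robust trend 1, the covariate 1, and no intensity trend, no moderation and the 6 arrays alone 0 each (1734, 1597 and 904 at an unadjusted p under 0.05). The deposited values gave 9 (5 higher, 4 lower, against 2 and 4), and leaving out 1 array 0 to 35. Between propiconazole and triadimefon, with 0 calls by limma (803 at an unadjusted p under 0.05), array weights gave 45 and leaving out 1 array 0 to 0.

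Camera with an estimated correlation called 0 lists in all 6 comparisons (5, 4, 2, 3, 5 and 6 at an unadjusted p under 0.05). Fry called 10 lists for myclobutanil, 5 for propiconazole and 1 for triadimefon against control, 1 between myclobutanil and propiconazole, 4 between myclobutanil and triadimefon and 1 between propiconazole and triadimefon. Leaving out 1 array gave 6 to 13, 7 to 9, 3 to 10, 6 to 7, 6 to 14 and 8 to 13 lists in that order. The excess covariance of responses was 0.166, 0.159 and 0.155 when taken over genes called with at least 1 compound, which are larger by selection, and 0.0117 to 0.0180, 0.0128 to 0.0165 and 0.0125 to 0.0182 without 1 array.

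The replicate numbers do not pair the arrays: deviations of the 18 pairs of arrays with the same number correlated at -0.494 to 0.495 (median -0.0265), 3 of them above 0.1, and 3 of 12 arrays were closest to their own number. With the replicate block limma made 180, 121 and 87 calls against control and 0 between myclobutanil and triadimefon (1526 at an unadjusted p under 0.05). An offset on the linear scale does not apply to log-like values and was not run, and quantile normalization is the reported setting. No scaling moved the median of all genes by more than 0.1.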

Other observations

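The tests on the cholesterol and clock genes were chosen after the results were seen, and the tests on other splits of the arrays before. With propiconazole and triadimefon the inducible chaperone gene Hspa1a stood at 1.92 ± 0.61 and 1.81 ± 0.61 against control (limma adjusted p = 0.166 and 0.23), and Hsph1 at 1.04 ± 0.36 and 0.94 ± 0.36. With myclobutanil the phosphatase gene Dusp1 stood at -0.81 ± 0.39 and Hspa1a at 0.82 ± 0.61 (limma adjusted p = 0.26 and 0.455). None of these passed the test.

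Hsd17b2 stood at -0.52 ± 0.28, 0.90 ± 0.28 and 1.19 ± 0.28 with myclobutanil, propiconazole and triadimefon against control. It stood at -1.42 ± 0.28 and -1.71 ± 0.28 between myclobutanil and the other compounds (limma adjusted p = 0.175 and 0.0812). Among acute phase genes, Lcn2 stood at 2.13 ± 0.60 with myclobutanil and A2m at 1.22 ± 0.49 with propiconazole (limma adjusted p = 0.0916 and 0.281). These genes were picked after their values were seen, and none passed the test.

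Cholesterol synthesis genes averaged -0.395 in propiconazole against triadimefon, at doses of 300 and 175 mg/kg/day. The mean was -0.476 (SE 0.111) with the 3' minus 5' difference as a covariate, which argues against RNA quality as the whole cause. Over the 6 arrays left out in turn the value nearest to 0 was -0.303 (SE 0.113), which argues against a single array, and the deposited values gave -0.397 (SE 0.0992), which argues against the quantile normalization. The compounds, their doses or a different hour of sampling may account for the difference, as a hypothesis, and the design does not separate these. The labels give no hour, and clock output genes minus activators differed by -0.519 (SE 0.162) between the same groups. Chance stays open too. Camera with an estimated correlation gave an adjusted p of 0.0655, and fry did not call the list.

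In triadimefon against control, the mean of 8 clock output genes minus that of 3 activators was 1.06 (SE 0.162), where myclobutanil gave 0.152 (-0.00679 without its replicate 01, 0.244 without its replicate 03) and propiconazole 0.544. With the 3' minus 5' difference as a covariate it was 1.05 (SE 0.171), which argues against RNA quality. A different hour of sampling may produce the same opposite shift, and it cannot be told apart from an effect of the compound, because the labels give no hour for each animal. Between compounds the same value was -0.392 for myclobutanil against propiconazole (-0.255 without propiconazole replicate 03), -0.911 for myclobutanil against triadimefon and -0.519 for propiconazole against triadimefon.

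The 10 splits of 6 arrays into groups of 3 are too few for a share under 0.05. The real and the highest other count of limma calls were 395 and 0, 311 and 0, and 167 and 0 against control for myclobutanil, propiconazole and triadimefon (as large in 1, 1 and 1 split). They were 0 and 1 between myclobutanil and propiconazole (as large in 10), 6 and 0 between myclobutanil and triadimefon (1) and 0 and 0 between propiconazole and triadimefon (10), with unadjusted counts for the real splits of 2200, 1653 and 803. For lists called by camera the real and highest other counts were 10 and 5 (1 split as large), 10 and 6 (1) and 6 and 12 (5) against control. Between compounds, in the same order, they were 7 and 11 (4), 9 and 8 (1) and 11 and 12 (4). For the covariance excess of responses, 2, 3 and 1 of 100 drawn splits of 9 arrays were as large as the real 0.0147, 0.0145 and 0.0152, and the highest other values were 0.0161, 0.0154 and 0.00867. As the splits mix in control arrays, the shares cannot test sharing between compounds. They are unadjusted over the 3 pairs, which share controls, and other splits gave larger values for myclobutanil with either other compound.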
